A study of Homo sapiens with 4 samples.

How the data were processed

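OCT4-bound RNA was measured by HITS-CLIP in H1 cells with a tandem affinity tag at POU5F1. The series has 4 samples in 2 groups, 2 OCT4 IPs and 2 Inputs, grouped by their titles. Per the labels' protocols, cells were irradiated at 254 nm with 400 mJ per square cm, lysates were treated with DNase, the protein was captured on FLAG beads, RNA was trimmed on the beads with micrococcal nuclease, complexes were cut from a gel, and libraries were made with a kit that keeps the strand. Per the submitters' processing notes, bcl2fastq and TopHat2 were used and the build was GRCh38. Versions of these tools, the peak caller, its thresholds, the way the Input was used and the treatment of duplicate reads are not given in the sources used here.

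The values come from 1 deposited peak list per IP. The tag count per peak is a whole number that the authors deposited without normalization. The maximal height of a peak is a coverage signal, also as deposited by the authors. The lists further hold position, strand, length, the share of the peak in each region class and 1 gene ID, all as deposited. Positions count from 1. The smallest count was 3 tags, which was taken as the floor of the lists. Peak numbers run to 349170 and 557714, so the lists are parts of longer series of peaks. Gene names were found for 9536 of 9655 gene IDs in replicate 1 and for 10629 of 10747 in replicate 2. Gene bounds and biotypes were taken from RefSeq genes of GRCh38.p14 by symbol, which gave bounds for 90.8% and 91.0% of peaks with a gene ID. Each peak was put in the class that held most of it, and a sense peak is one in neither the antisense nor the intergenic class. The class intron also takes parts of a peak outside the exons of the 1 assigned gene, as on the mitochondrial genome.

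The plan foresaw enrichment over Input. The lists used here give IP tags and no Input value, fold or p, so tag counts stand in their place, the largest peak of a gene is the one with most tags, and no test of IP against Input was made. For peak overlap, peaks were placed at random 1000 times within the bounds of their gene, on the same strand. Where RefSeq gave no bounds, the span of the gene's peaks with 5000 bp on each side was used, and intergenic peaks were placed within the span of their chromosome. Only 100 placements were made for shuffled shares by region class or tag count, for gene ends, and for antisense and opposite-strand overlap. Shared genes were tested with Fisher's exact test among 62700 annotated genes, and with 1000 draws matched in 20 bins of gene length. Gene lists were tested with Fisher's exact test among genes with a sense peak in either replicate, with Benjamini-Hochberg adjustment over 12 lists and a threshold of 0.05, and with 10000 matched draws, adjusted over 11 lists where gene length was matched. Shares have exact Clopper-Pearson 95% intervals, and tag counts have exact Poisson 95% intervals. The odds of overlap between region classes were pooled over 8 bins of tag count by the Mantel-Haenszel method. With 2 lists, no test has samples as its units, and a mean over the replicates is given with its SD. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

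The tests were tried on simulated data. For peak overlap, with 25174 simulated peaks, 0 planted shared peaks gave a permutation p of 0.42, 200 planted gave an excess of 165 and 1000 planted gave an excess of 991. For the fixed gene lists, 200 sets of 12 lists with the real numbers of members were drawn at random among the 11859 genes with a sense peak in either replicate, and 6 sets had a list past the adjusted threshold. These draws take no account of gene length, so they do not show how often lists of long or short genes pass through length alone. A list with 70% of its members planted in both replicates passed in 96.5% of sets at 51 members with a peak, 59% at 23, 12.5% at 11 and 0% at 4, so the smallest lists had little chance to pass with an excess.

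Choices made before the data were examined were the groups, the tests, the 12 gene lists, the rule for named genes and most alternatives. Named genes are the 10 with most peaks overlapping between the replicates, the 10 overlapping peaks with the largest lower tag count (at most 1 per gene, used because no enrichment was given), POU5F1, and up to 4 members per list with most overlapping peaks, ties broken by tags. Members without a peak may be named as such, which is how SOX2 enters, and 1 gene that the rule takes is not reported here. The lists are pluripotency genes, lineage regulators, long non-coding RNAs, small structured RNAs, mitochondrially encoded genes, histones, ribosomal proteins, splicing factors, chromatin regulators, signalling genes, long cell adhesion and neural genes, and mesenchymal markers of other cell types. Alternatives tried were a minimum of 10 tags, a reciprocal overlap of 50%, strand ignored, shuffling within the chromosome, length-matched draws, at least 2 peaks per gene, height in place of tags, pairs without the 3-tag floor, overlapping peaks only, shares of bases or genes, and each replicate left out. Added after seeing the data were a gap of 500 bp, lists without mitochondrial and ribosomal RNA repeat peaks, shares of tags, the 10-tag minimum for regions and lists, and draws matched on peak number, on length with biotype, or on nearest length. The test of 6-base words and of the octamer motif was not run, since no genome sequence was used here.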

Results

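RNA bound by OCT4 was mapped in H1 cells, an established human embryonic stem cell line. OCT4, the product of POU5F1, is a DNA-binding transcription factor of the pluripotency network, and in these cells a tandem affinity tag had been inserted at the gene's own locus so that the tagged protein could be pulled down with FLAG beads. The method was HITS-CLIP, in which ultraviolet light fixes RNA to the proteins it touches before the protein is purified and the attached RNA is sequenced. The series holds 2 OCT4 immunoprecipitates (IP) and 2 Input samples, and the analysis rests on 1 list of peaks per IP. A peak is a stretch of genome on 1 strand where sequenced tags pile up. The labels do not say whether the 2 IPs came from separate cultures, so the spread between them may be technical, and all p-values below describe peaks or genes within these 2 lists. No Input values were used here, so levels are IP tags and not enrichment over Input.

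Replicate 1 listed 25174 peaks holding 142344 tags, and replicate 2 listed 29231 peaks holding 205721 tags. The tagged gene itself, POU5F1, had no peak in replicate 1. In replicate 2 it had 1 peak of 16 tags (95% Poisson interval 9.15 to 26.0) on chromosome 6 at 31165127 to 31165238, minus strand, wholly in coding sequence. Most peaks were small. The median was 4 tags in both lists, with an interquartile range of 3 to 6 in replicate 1 and 3 to 8 in replicate 2, and no listed peak held fewer than 3 tags. Peaks with exactly 3 tags made up 40.7% of list 1 and 25.5% of list 2. Peaks with 10 or more tags numbered 2220 and 5009. The largest peak of replicate 1, by tags, held 7860 on the mitochondrial genome at 655 to 3992, over the mitochondrial ribosomal RNA genes, and took 5.52% of that list's tags. The largest of replicate 2 by tags held 711, also on the mitochondrial genome. Tags in peaks are only part of a library, whose full depth is not given in the sources used here. Intervals on tags and shares cover counting error only.

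The first comparison asked whether the same sites carried a listed peak in both replicates. Few did, but many more than shuffling gave. In replicate 1, 2029 peaks (8.06%, exact Clopper-Pearson 95% interval 7.73 to 8.40) shared at least 1 bp on the same strand with a peak of replicate 2. Shuffling the peaks within their own genes gave 309.4 ± 16.4 (SD over 1000 shuffles), a ratio of 6.56 with a two-sided permutation p of 0.001, the smallest 1000 shuffles can give. In replicate 2, 1995 peaks (6.82%, 6.54 to 7.12) overlapped against 305.7 ± 16.9 shuffled, a ratio of 6.53 with the same permutation p of 0.001. Peaks in 5' UTRs overlapped most often, 25.4% in replicate 1 and 18.7% in replicate 2, and those between genes least often, 2.48% and 2.05%. Intronic peaks overlapped in 7.32% and 6.58% of cases, against 1.30% and 1.13% when shuffled. Shuffled shares were 2.17% and 1.57% for 5' UTR peaks. For intergenic peaks they were 0.18% and 0.15%, but these were placed over whole chromosomes, so their level is not like that of the other classes. With peaks compared within 8 bins of tag count, a 5' UTR peak had 2.34 times the odds of overlap of an intronic peak in replicate 1 (95% interval 1.93 to 2.83) and 1.98 times in replicate 2 (1.64 to 2.39). So compared, intergenic peaks had 1.03 (0.84 to 1.27) and 1.09 (0.88 to 1.34) times the odds of intronic ones, so their lower share was not seen within these bins. Antisense peaks had 1.43 (1.23 to 1.65) and 2.19 (1.89 to 2.54) times the odds, and coding peaks 1.47 (1.29 to 1.67) and 1.08 (0.95 to 1.22). The share rose with tags, to 26.3% of peaks with 10 or more tags in replicate 1 and 18.4% in replicate 2. The shuffle holds gene, strand and length but not exon position, and a shuffle over the whole chromosome gave ratios of 37.0 and 36.7. With no Input value used, the excess is not shown to come from binding by OCT4, and an unmatched site is not shown to be unbound.

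**Figure D1:**
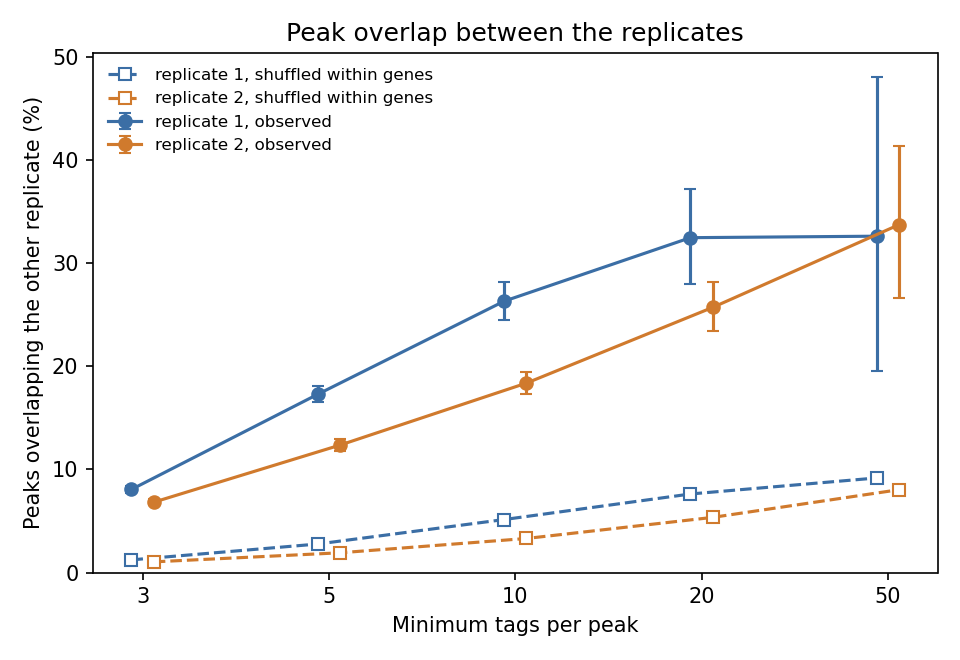
Share of peaks (%) that overlap a same-strand peak of the other OCT4 IP, by the minimum tags per peak. Filled points are observed shares with exact 95% intervals and open squares the mean after shuffling within genes. Observed shares rise from 8.06% and 6.82% over all peaks to 32.6% and 33.7% at 50 or more tags, above the shuffled level throughout.

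The overlapping peaks formed 2049 pairs, and their tag numbers went together between the replicates. Across pairs, Pearson's r of log2 tags was 0.72 and Spearman's rho was 0.68 (95% bootstrap interval 0.65 to 0.70). Peaks are not independent replicates, so no p-value is attached. Of the 10 pairs with the highest lower tag count, at most 1 per gene, 3 lay inside annotated 45S ribosomal RNA repeats on chromosome 21. Their assigned genes are ENSG00000278996 with 275 tags in replicate 1 and 250 in replicate 2, ENSG00000280441 with 242 and 204, and ENSG00000275783, which takes the 62 tags of replicate 1 only, since the 116 tags of replicate 2 there are assigned to ENSG00000276737. All 3 lie in copies of the same repeat. How reads were placed among the copies was not examined, so these pairs may not be separate sites. A further pair, assigned to MT-ND5 in replicate 1, lay on the mitochondrial genome with 153 and 711 tags. Keeping 1 pair per gene left out others above the lowest of the 10. In the ribosomal RNA repeats these had 91 and 90 or 60 and 79 tags, and on the mitochondrial genome 105 and 711.

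The other 6 pairs sat at the start of protein-coding genes. SCAF4, which codes for a protein that binds the tail of RNA polymerase II, had 74 tags in replicate 1 (95% Poisson interval 58.1 to 92.9) on chromosome 21 at 31731663 to 31732107, 86% of it in the 5' UTR, and 103 in replicate 2 (84.1 to 124.9). RBM15B, a partner of the RNA m6A methylation machinery, had 70 and 89 tags in its coding sequence on chromosome 3 at 51391651 to 51392614. CCN1, a secreted matrix protein, had 61 and 69 tags on chromosome 1 at 85580771 to 85581109, mostly 5' UTR. AKIRIN1 had 60 and 86 tags on chromosome 1 at 38991318 to 38991664, mostly coding. RASD1, a small GTPase, had 60 and 87 tags on chromosome 17 at 17496038 to 17496371. LAMA5, a laminin chain of basement membranes, had 58 and 122 tags on chromosome 20 at 62366871 to 62367295. Coordinates are those of replicate 1 in GRCh38.

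**Figure D2:**
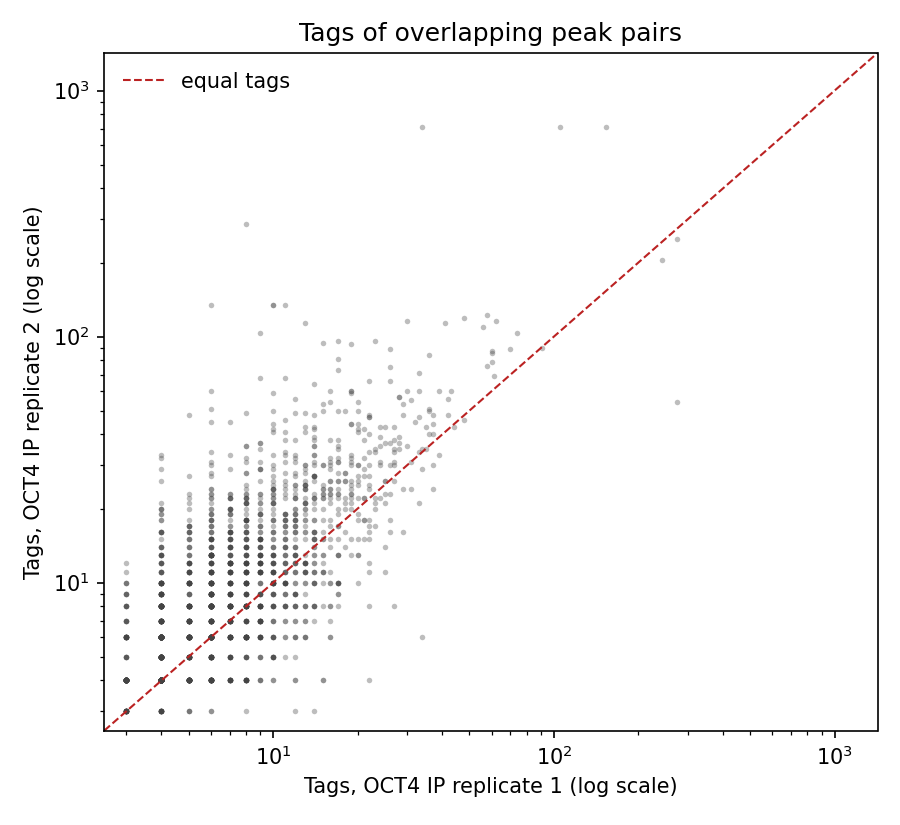
Tags of the 2049 overlapping peak pairs in OCT4 IP replicate 1 (x axis) and replicate 2 (y axis), both on log scales, 1 point per pair. The dashed line marks equal tags. Most pairs lie above it, with a median log2 ratio of replicate 2 to replicate 1 of 0.42, and Spearman's rho is 0.68.

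The next comparison asked which genes carried OCT4 peaks on their own strand in both replicates. Of the 7591 named genes with such a sense peak in replicate 1 and the 8825 in replicate 2, 4557 were shared. That is 38.4% of the 11859 genes with a sense peak in either list. Chance among 62700 annotated genes would share 1068, a ratio of 4.27 with an odds ratio of 17.9. Long genes carry peaks more often. Draws matched on gene length shared 2768 ± 30.9 (SD) against 4331 observed, which lowers the ratio to 1.56 (permutation p 0.001, the smallest possible). These draws hold neither biotype nor the level of the RNA in the cells, so the excess is not shown to come from binding by OCT4.

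MEGF6, COL5A1 and CCDC85C headed the genes with most overlapping peaks. MEGF6, on chromosome 1, had 13 sense peaks in each replicate, of which 6 in replicate 1 and 7 in replicate 2 overlapped. CCDC85C, on chromosome 14, had 10 and 6 sense peaks, of which 6 and 5 overlapped, with its largest peaks of 36 and 51 tags in coding sequence. COL5A1, a fibrillar collagen gene, had 12 sense peaks in replicate 1 and 22 in replicate 2, of which 6 overlapped in each. RBFOX3, which codes for the neuronal splicing regulator NeuN, had 8 in each. NOTCH1, a receptor of cell-to-cell signalling, had 5 and 4 sense peaks with largest peaks of 35 and 71 tags, both intronic but at places that did not overlap. The polarity gene SCRIB had 5 in each, with largest peaks of 37 and 34 tags in coding sequence that did not overlap each other. NYAP1, DDX51, KIF26A and the unnamed gene ENSG00000264187 completed the group, each with 3 or 4 overlapping peaks per list.

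Peaks were spread over introns, exons, the opposite strand of genes and the space between genes. Introns held 30.3% ± 0.66 of peaks (SD, n = 2), sense exons 24.1% ± 3.56, the antisense strand of genes 22.3% ± 2.91 and intergenic sequence 23.3% ± 1.30. Among sense exons, coding sequence held 16.1% ± 2.83, 3' UTRs 3.44% ± 0.52, 5' UTRs 3.27% ± 0.13 and non-coding exons 1.29% ± 0.07. Peaks with more tags were found more in exons. Of peaks with 10 or more tags, sense exons held 56.3%, antisense strands 8.21% and intergenic sequence 2.93%. Of peaks overlapping between the replicates, sense exons held 45.0% ± 1.29 and intergenic sequence 7.08% ± 0.51, while the antisense share of 19.6% differed from that of all peaks by less than the spread between replicates. These classes are the annotation given in the lists, and a peak was placed in the class that held most of it.

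**Figure D3:**
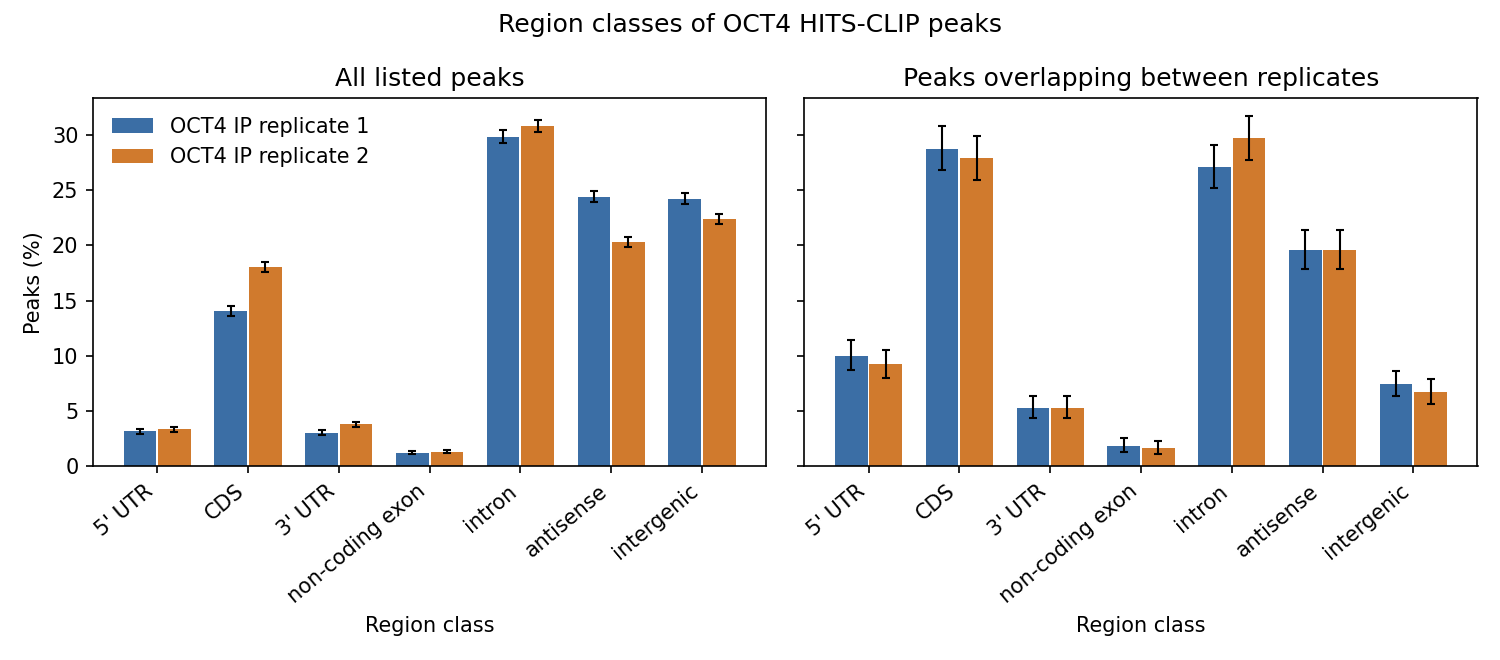
Share of peaks (%) in each region class for OCT4 IP replicates 1 and 2, over all listed peaks (left) and over peaks overlapping between the replicates (right). Bars start at 0 and carry exact 95% intervals. Coding sequence rises from 16.1% of all peaks to 28.3% of overlapping peaks on average, and intergenic sequence falls from 23.3% to 7.08%.

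Peaks gathered at the 5' ends of genes on both strands, a comparison chosen after seeing the data. Of sense peaks, 14.9% in replicate 1 (95% interval 14.3 to 15.6) and 15.4% in replicate 2 (14.9 to 16.0) had their summit within 1000 bp of the annotated 5' end. Shuffling within genes gave 3.81% and 4.04%. Antisense peaks did so in 14.9% (14.0 to 15.9) and 14.2% (13.3 to 15.2) of cases, against 4.55% and 4.41% shuffled. Within 1000 bp of the 3' end lay 5.04% and 5.40% of sense peaks, against 3.82% and 4.03% shuffled. Exonic peaks lay there in 10.3% and 9.95% of cases and intronic ones in 0.94% and 1.14%, a split that the classes themselves favour, since genes end in exons and the shuffle does not hold exon position. Gene bounds here are those of RefSeq on GRCh38.p14.

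**Figure D4:**
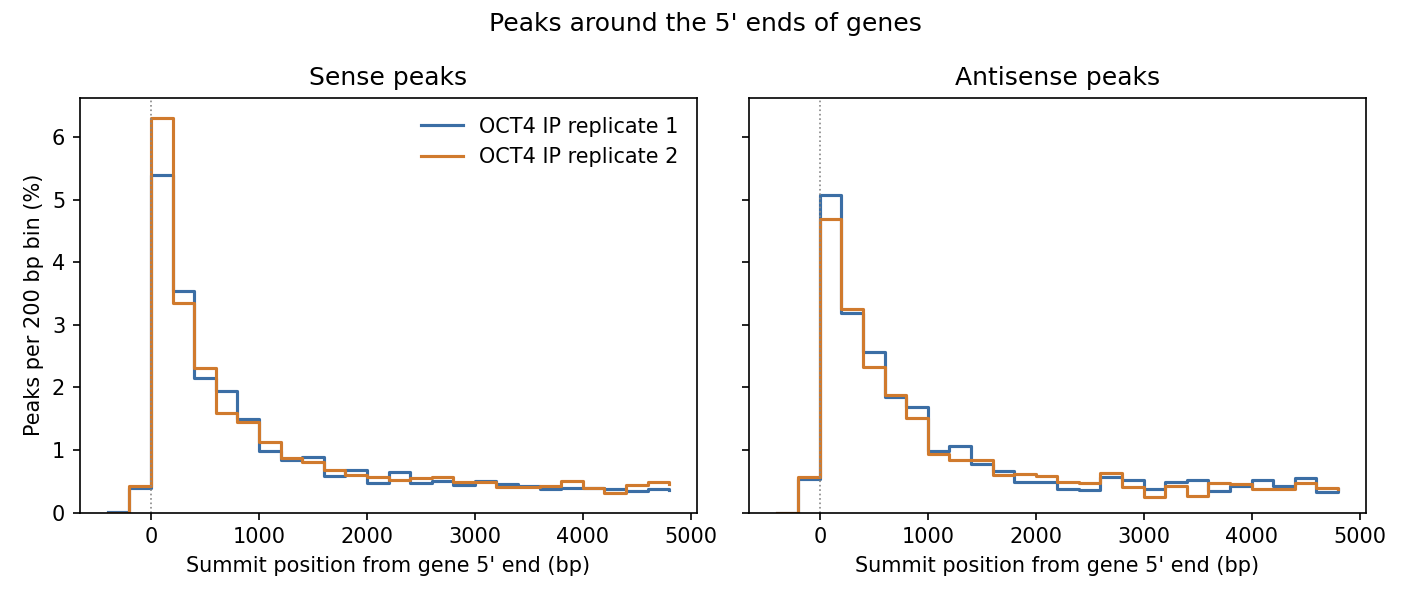
Share of sense peaks (left) and antisense peaks (right) per 200 bp bin, by the distance in bp of the summit from the annotated 5' end of its gene, for OCT4 IP replicates 1 and 2. Peaks are assigned to genes, so few lie upstream of 0. Both strands are highest in the bin that starts at 0 and decline over the next 1000 bp.

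The question of which RNA classes carried peaks was taken from the biotypes of the genes with sense peaks. A biotype was known for 11750 of 12934 sense peaks in replicate 1 and for 15335 of 16761 in replicate 2. The other sense peaks, whose gene had no RefSeq bounds, are left out of these shares. Of the peaks with a biotype, protein-coding genes held 93.9% in replicate 1 (95% interval 93.4 to 94.3) and 94.0% in replicate 2 (93.6 to 94.3). Long non-coding RNA genes held 5.06% (4.67 to 5.47) and 4.86% (4.53 to 5.22). Pseudogenes and other known biotypes held the remaining 1.09% and 1.17% of the peaks with a biotype.

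Fixed groups of genes were then asked how often their members had a sense peak in both replicates, among all genes with one in either (Fisher's exact test, two-sided, Benjamini-Hochberg over 12 lists). The pluripotency genes did not pass this test. Of 40 members, 10 had a sense peak in replicate 1, 21 in replicate 2 and 8 in both (odds ratio 0.85, adjusted exact p = 0.91). In replicate 2 alone, 20 of the 39 members with a known length had a sense peak against 11.1 ± 2.67 (SD) in length-matched draws, adjusted permutation p = 0.0049, or 0.083 with biotype matched too. FOXD3, a regulator of early embryonic cells, had 42 tags in replicate 1 and 48 in replicate 2, mostly coding, on chromosome 1 at 63323001 to 63323629. JARID2, a Polycomb cofactor, had largest peaks of 11 and 34 tags in its introns. FGF4 had 6 tags in each, and DNMT3B, a DNA methyltransferase, had no sense peak in replicate 1 and 1 of 315 tags (281 to 352) across the 5' UTR and intron in replicate 2. SOX2 had no peak in either list. The lineage regulators, which direct differentiation into germ layers, shared 0 of their 11 genes with a peak (36 members, odds ratio 0, adjusted exact p = 0.022). They did not pass against length-matched draws, which gave 4.47 ± 1.86 (SD, adjusted permutation p = 0.058), but passed with biotype matched too (0.026). Their peaks were low. TBX6 had a largest peak of 9 tags and ZEB1 of 6, both in replicate 2, and ONECUT1 had 8 and LHX5 had 5, both in replicate 1.

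Long non-coding RNAs had peaks in both replicates more often than the background. Of 41 members, 21 had a sense peak and 15 had one in both (odds ratio 4.02, adjusted exact p = 0.011). CASC15 had 9 sense peaks in replicate 1 and 7 in replicate 2, all of at most 6 and 8 tags. SNHG14, the host transcript of the Prader-Willi region, had 1 and 6. LINC-PINT had 2 and 1, and FIRRE, a nuclear RNA from the X chromosome, had 3 and 5. The largest peaks of CASC15, SNHG14, LINC-PINT and FIRRE lay wholly in introns in both replicates. No sense peak of FIRRE overlapped between the replicates. Of 29 small structured RNAs, 1 had a peak, and length-matched draws expected 0.055 in replicate 1 and 0.056 in replicate 2, so genes this short rarely have one. The peak was that of SCARNA2, a Cajal body RNA, with 210 tags (183 to 240) in replicate 2. Mitochondrially encoded genes had a peak in 4 of 37 members in each replicate and shared 0 (odds ratio 0, adjusted exact p = 0.054). Each long mitochondrial peak is assigned to 1 gene, so MT-RNR1, with 7860 tags, MT-ND5 and MT-CYB appear for replicate 1 and MT-TL2, with 711 tags, for replicate 2, although the last overlaps the peaks at MT-ND5 and MT-CYB.

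Chromatin regulators were also shared more often, with 30 of the 51 genes that had a peak (59 members, odds ratio 2.30, adjusted exact p = 0.011). CHD7, a chromatin remodeller, had 5 and 3 sense peaks, of which 2 overlapped in each. KMT2D, a histone H3 methyltransferase, had largest peaks of 55 and 25 tags in coding sequence that did not overlap each other. MTA1, of the NuRD complex, had 7 and 8 sense peaks. Splicing factors shared 17 of 35 genes (59 members, odds ratio 1.52, adjusted exact p = 0.30). SRRM2 had 58 and 76 tags in coding sequence on chromosome 16 at 2760281 to 2760499. HNRNPF had largest peaks of 17 and 38 tags, HNRNPDL of 9 and 29 and SRSF7 of 12 and 13, all within introns. Signalling genes shared 13 of 22 (32 members, odds ratio 2.32, adjusted exact p = 0.087). FGFR1 had an intronic peak of 25 and 43 tags and AKT1 a 5' UTR peak of 14 and 27. GSK3B had a 5' UTR peak of 60 tags in replicate 1 and no sense peak in replicate 2, and BMPR1A had largest peaks of 7 and 56 tags that did not overlap.

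Ribosomal protein genes were shared less often than the background, in 4 of the 32 with a peak (84 members, odds ratio 0.23, adjusted exact p = 0.010). Length-matched draws gave no such deficit, with 4 shared against 5.12 ± 2.15 (SD, adjusted permutation p = 0.77). In replicate 2 alone 21 had a peak against 13.5 ± 3.31 (SD, adjusted permutation p = 0.044), but against 18.8 ± 3.75 with biotype matched too (adjusted permutation p = 0.72). RPL13 had largest peaks of 10 and 23 tags and RPL23 of 9 and 15. RPLP1 had no peak in replicate 1 and 505 tags (462 to 551) in replicate 2, while RPL8 had 359 tags (323 to 398) in replicate 1 and no sense peak in replicate 2. Histone genes shared 3 of 12 (73 members, odds ratio 0.53, adjusted exact p = 0.47). In each replicate alone they lay above length-matched draws, with 9 against 1.65 ± 1.16 (SD) in replicate 1 (adjusted permutation p = 0.0011) and 6 against 2.09 ± 1.29 in replicate 2 (adjusted permutation p = 0.019), but did not pass with biotype matched too (adjusted permutation p = 0.093 and 1). H4C6 had 32 and 45 tags and H2BC14 had 8 and 28, mostly coding. H1-4 had 18 and 97 tags at places that did not overlap, and H3C6 had 54 tags in replicate 2 alone. The mesenchymal markers, a list for other cell types, shared 3 of 4 genes (14 members, odds ratio 4.81, adjusted exact p = 0.24). COL1A1 had 4 sense peaks in replicate 1 and 13 in replicate 2, with 99 and 528 tags in all. COL1A2 had 2 peaks in replicate 2 alone, and PDGFRB and ACTA2 had largest peaks of at most 9 and 6 tags.

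The list of long cell adhesion and neural genes stood furthest above the background, with a sense peak in both replicates in 26 of 30 members (odds ratio 10.5, adjusted exact p = 7.9e-07). The peaks were small. PARD3, a polarity gene, had 8 sense peaks in replicate 1 and 10 in replicate 2, with largest peaks of 7 and 12 tags. CADM2 had largest peaks of 7 and 5 tags, and WWOX of 5 in each. The largest peaks of PARD3 and of WWOX did not overlap between the replicates. Of the 5 lists past the threshold, long non-coding RNAs (adjusted permutation p = 0.0051), chromatin regulators (0.0022) and the long genes (0.0011) also passed against length-matched draws, though for the long genes those draws were shorter than the list. Lineage regulators did not pass there (adjusted permutation p = 0.058), but did with biotype matched too (0.026). Counting only overlapping peaks, long non-coding RNAs had 3 of 21 genes against 2.16 expected, chromatin regulators 7 of 51 against 5.23 and the long genes 5 of 30 against 3.08 (adjusted exact p of 0.80 or more), and the other 2 lists, both with a deficit, could not pass because too few genes were expected.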

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

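The tests of the 3-tag floor, of strandless fragments at 10 or more tags and of nearest gene length were chosen after their results were seen, and the comparisons of antisense overlap and of short gaps between genes were added afterwards too. The strand of a listed peak opposite another, and the ribosomal and mitochondrial peaks, lie outside the planned comparisons. A peak on the opposite strand within the same list faced 1065 peaks of replicate 1 (4.23%, 95% interval 3.99 to 4.49) and 958 of replicate 2 (3.28%, 3.08 to 3.49). Shuffling within genes gave 152 and 216 (permutation p 0.01, the smallest that 100 shuffles give). Peaks in annotated ribosomal RNA repeats held 1410 tags in replicate 1 and 980 in replicate 2, which is 0.99% and 0.48% of tags in peaks. Peaks of the mitochondrial genome held 8240 and 1115 tags, or 5.79% and 0.54%. No biological explanation was tested for the patterns below, since the design has no second condition.

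Few peaks overlapped a same-strand peak of the other replicate. Loss by sampling near the 3-tag floor is argued against as the whole cause, because only 33.5% of the 215 peaks with 50 or more tags overlapped the other list (95% interval 27.2 to 40.2). Peak edges placed differently in the lists are argued against too, since a gap of 500 bp raised the share of replicate 1 peaks with a counterpart only to 12.7%. Removal of counterparts by the comparison with the Input stays open: 1279 peaks with 20 or more tags had no counterpart, and the values used here hold no Input or IP counts at those places. The treatment of duplicate reads is not given, so 50 tags may stand for fewer molecules.

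About 22.3% of the peaks lay antisense to a gene. Genomic DNA spread evenly over the genome is argued against as the whole source. Antisense peaks overlapped the other replicate in 6.46% and 6.58% of cases, against 0.99% and 0.98% shuffled. This covers evenly spread DNA only, since DNA gathered at particular places could overlap as well and was not tested. The density in genes was at least 1.64 times that outside. It was 1.57 and 1.40 times when only gaps of up to 500 kb between genes were counted, so the density alone does not decide. Strandless fragments alone would give near-equal antisense and sense intronic peaks. At 10 or more tags antisense peaks were at most 24.8% of the 2 classes together, which argues against such fragments as the source of all these peaks. It does not decide for the antisense peaks by themselves. Sense RNA adds to the intronic class, and the antisense class also takes peaks opposite exons. At 3 tags antisense peaks were 54.5% of the 2 classes in replicate 1 and 61.1% in replicate 2 (59.5 to 62.7). Since that interval spans the limit of 60% set beforehand, strandless fragments stay open there as well. An antisense peak faced a listed peak of any class on the opposite strand in 6.89% and 6.70% of cases. In pairs with a sense peak of the same gene, the sense peak had more tags in 345 pairs against 29 in replicate 1. In replicate 2 it did so in 355 against 21, and the median ratios were 1.80 and 2.75. That direction goes with reads of abundant RNA written to the wrong strand. The sense peak had 5 times the tags or more in at most 25.2% of pairs, below the limit set beforehand for such reads as the source of most pairs. That limit does not decide, because an antisense peak is listed only with 3 or more tags, which favours low ratios. It also says nothing of the other antisense peaks.

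Nearly all members of the list of long neural genes, 26 of 30, had a sense peak in both replicates. Draws in 20 length bins gave 14.0 ± 2.70 (SD), central 95% 9 to 19, and so put the list outside the limit set beforehand, but that limit was wrong because the list's median length of 1433272 bp is 5.34 times that of the genes in its bin. Draws from the 15 protein-coding genes nearest in length on each side gave 21.7 (17 to 26), which takes in 26. The answer changes with the width of the match: 5 genes on each side gave 23.2 (19 to 27) and 30 gave 19.3 (14 to 24). Gene length therefore may account for the list, and the draws do not settle whether it does so fully.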

How the results depend on the processing

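The settings chosen after seeing the data are the 500 bp gap, shares of tags, the 10-tag minimum for regions and lists, the lists without mitochondrial and ribosomal repeat peaks, and the draws matched on peak number or on length with biotype. No paired analysis was possible because the lists used here give no Input values to pair with the IPs. For the same reason a stricter fold or p, pairs without peaks at the Input floor and pooled IP against pooled Input were not run. A second region annotation, shuffled sequences and peaks outside repeats were not run, since no exon models or genome sequence were used. Replicate overlap stayed above the shuffled level in every setting run. It ran from 4.93% at a reciprocal 50% in replicate 2 to 22.5% in replicate 1 with both lists kept to 10 or more tags. Shared genes stayed above chance, with ratios from 1.56 to 8.55. Keeping 10 or more tags lowered the lists to 2220 and 5009 peaks by construction. Spearman's rho was 0.74 with reciprocal overlap and 0.65 without the 3-tag floor. Overlapping peaks lay in sense exons in 45.0%, introns in 28.4% and intergenic sequence in 7.08% of cases. By tags, the shares were 35.4% sense exons, 34.6% introns, 16.1% antisense and 13.9% intergenic. With 10 or more tags they were 56.3%, 32.6%, 8.21% and 2.93%, and by bases introns held 34.4% and intergenic sequence 21.6%. The cause was not tested. Where the biotype was known, protein-coding genes held 91.6% by genes and 95.4% by overlapping peaks, and long non-coding RNA genes 6.86% and 3.22%. Of the 12 lists, 5 passed in the main test, 0 with overlapping peaks, 3 with length-matched draws, 0 with 10 or more tags and 0 matched on peak number. The draws leave out the mitochondrially encoded genes, which have no length here, so 11 lists were tested there. Of the 5, only 3 could have passed with overlapping peaks and 3 with 10 or more tags, the others having too few genes or too few expected for a deficit. Matching on peak number fixes the outcome only for genes with 1 peak, which cannot be shared. Draws so matched gave 32.6 ± 2.31 (SD) for chromatin regulators against 30 observed, and 24.99 ± 1.48 for the long genes against 26. Ribosomal protein genes had 4 against 4.22 ± 1.26. Long non-coding RNAs had 15 against 12.8 ± 1.44 and lineage regulators 0 against 0.99 ± 0.71. None of the 5 was thus shown to depart from what its peak number gave. Peak number is itself tied to being shared, so these draws do not show the calls to be wrong. With 10 or more tags the odds ratio was 0.37 for long non-coding RNAs, from 1 of 8 genes (exact p = 0.46), and 0 for the long genes, from 0 of 2 (exact p = 1), too few to show a direction. Leaving out a replicate in turn moved sense exons from 21.5% to 26.6% and antisense peaks from 20.3% to 24.4%, and 4 to 6 lists passed against length-matched draws. These were not the same lists. Replicate 2 alone passed pluripotency (adjusted permutation p = 0.0049), splicing factor (0.017) and ribosomal protein genes (0.044, above the draws) and not long non-coding RNAs (0.096), and with biotype matched too these 4 turned, to 0.083, 0.18, 0.72 and 0.00055. Histones (0.019 to 1) and the long genes (0.011 to 0.0995) lost the call there as well, and in replicate 1 alone histones (0.0011 to 0.093) and chromatin regulators (0.034 to 0.093) did. Library depth is unknown, so a gene without a peak is not shown to be unbound.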

Other observations

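All tests here were chosen after seeing the data. Protein-coding families defined by the letters that start their symbols were compared with draws matched on length and biotype, for the 96 families with 20 or more members. Olfactory receptors, which are expressed in nasal sensory neurons, had 0 of 382 members with a sense peak in both replicates against 27.3 ± 4.76 drawn (SD, adjusted permutation p = 0.0096 over 10000 draws). Cytochrome P450 genes, named CYP, had 0 of 56 against 10.1 ± 2.82 (adjusted permutation p = 0.014). No family passed with more than drawn. The collagens, named COL, had 23 of 44 against 16.0 ± 3.04 (adjusted permutation p = 0.21). In replicate 2, COL1A1 had 13 peaks in coding sequence, COL5A1 had 17, COL16A1 had 12 and COL27A1 had 10, against 3, 5, 7 and 2 in replicate 1. COL7A1 went the other way, with 12 in replicate 1 and 2 in replicate 2, and COL4A3, COL4A4 and COL25A1 had 3 each in replicate 1 and 0 in replicate 2.

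Several of the strongest peaks outside the mitochondrial genome were in 1 list only, and the genes below were chosen after their values were seen. In replicate 1, FTH1, the ferritin heavy chain, had 372 tags (95% Poisson interval 335 to 412) on chromosome 11 at 61967200 to 61967620, 46% of it in the 5' UTR, and FASN, the fatty acid synthase, had 124 (103 to 148) on chromosome 17 at 82096934 to 82098249. Neither had a sense peak in replicate 2. In replicate 2, BSG, a membrane glycoprotein, had 384 tags (347 to 424) in its 3' UTR on chromosome 19 at 582916 to 583488. SLC6A6, the taurine transporter, had 226 (197 to 257) on chromosome 3 at 14402590 to 14402946, and LIN28A, an RNA-binding protein of pluripotent cells, had 210 (183 to 240) on chromosome 1 at 26410784 to 26411187. None of these had a sense peak in replicate 1.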
